A study of Oryza sativa with 51 samples.

How the data were processed

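Gene expression was measured in leaves of rice (Oryza sativa, cultivar Koshihikari) grown in a field in Toyama in 2012. Plants had been transplanted on April 25 (early) or May 18 (late). Leaves were sampled every 2 h from 12:00 to 12:00 of the next day, once on July 10 and 11 and once on August 7 and 8, with 1 sample per time and no replicates. The 51 samples form 4 series named by month and transplanting. Plants were 76 and 53 days from transplanting in July (early and late) and 104 and 81 days in August.

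The samples were hybridized to 26 two-colour Agilent arrays of 156732 spots, of which 4854 are controls and 151878 are 60-base probes. On 25 arrays an early and a late sample of the same hour were labelled with opposite dyes. The remaining array carried the 1 sample of July 06:00, and its other channel belongs to no sample and was not used. All July arrays were scanned on 1 day and all August arrays on another, and no slide held both months, so month cannot be told apart from scan day. Within each series of both months the dye ran with time of day, in opposite order in early and late plants.

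The authors deposited 1 file per array, written by Agilent Feature Extraction 10.5.1.1. Per the file headers, the mean and background columns are scanner intensity values per spot with no background subtracted. Per the file headers, the processed signal columns are intensity values after background subtraction, detrending and dye normalization within the array. Per the file headers, the flag columns hold other values, 0 or 1 marks per spot. The authors gave no gene name or chromosome position for any probe: 151878 probes are described as unknown, 151878 are unmapped, and 0 identifiers matched a reference table of 39387 rice genes. Results are therefore given per probe, each identified by its name on the array and its 60-base sequence. The 17 gene lists by locus (187 loci), the 27 lists by product name and the tests of those lists could not be run.

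Mean intensities were background-corrected with normexp (offset 50), taken to log2 and quantile-normalized over the 51 channels in limma 3.58.1 (R 4.3.3, with statmod 1.5.0, version 1.17.8 of data.table and igraph 2.1.4). The 329 probes marked as non-uniform or as population outliers in any used channel were left out. Probes with an identical sequence were averaged, which left 148525 sequences. A sequence was tested if it was well above background, by the flag in the files, in at least 12 of the 51 samples, and 94092 sequences passed. No spot was saturated in a used channel. Each sequence is called a probe. Many probes share sequence and are likely to cover the same transcript. Joined by shared stretches of 25 bases, the 94092 probes form 61272 groups, so counts of probes are not counts of genes.

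1 model in limma held a mean, a 24 h cosine and sine and a 12 h cosine and sine for each series, plus a dye term (21 terms, 30 residual degrees of freedom). The array was a random block, with a correlation of 0.627 estimated on 3000 probes. Variances were moderated with an intensity trend, and p-values were adjusted by Benjamini-Hochberg over the 94092 probes with a threshold of 0.05. A rhythm was tested with an F test of the 24 h terms. Its range is the fitted log2 difference between peak and trough of the 24 h wave, and a range of at least 1 (2-fold) is called large. Fitted beside a 12 h wave, this range can exceed the span of the measured values. Means over the day were compared between transplantings, between months, and between the pair of series of similar age. The second 12:00 was compared with the first in a model with terms for the 12:00 samples (26 residual degrees of freedom, array correlation 0.558). With no replicates, the spread around the fitted curves served as the error in every test. The number of arrays limits the precision, and the standard errors given come from these models.

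Samples, comparisons, tests, alternatives and the rule for named probes were fixed before the data were examined. That rule asked for the 10 largest differences in each direction among described genes. With no descriptions the condition was dropped and, before results were seen, the number was lowered to at most 2 in each direction per comparison. Of the 20 probes with the largest rhythms, the first 4 are described. Array correlation in the 12:00 comparison was estimated in the model with the 12:00 terms. An exploratory fit had reused the other correlation, and its counts are given as an alternative. Leaving out 2 July arrays, leaving out each array in turn and that correlation were added after the data were seen.

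The model was tested on simulated data with normal noise of each probe's fitted spread and array correlation. Of 200 changed probes each, it recovered 87% of transplanting differences of 0.25 log2 and 93% of month differences of 0.5. It recovered 81% of rhythms in 1 series with an amplitude of 0.5 and 34.5% of those with an amplitude of 0.25. Unchanged probes made up 3.7% to 6.1% of the calls. The noise was drawn independently for each probe, so these shares need not hold for the real calls, where probes can vary together. Alternatives covered the authors' processed signals, 3 other normalizations, the filter, the curve, the dye term, the block, sample weights, the second 12:00 and log ratios within arrays. For each comparison except that of the noons, 100 groupings of the samples were fitted, the real one included. The array correlation of the others was estimated on 1000 probes. Probes that share 25 bases were paired to compare their values. The hour of a sample was read against the other month's fitted profiles of the 1000 probes with the largest rhythm F statistics in that month, on a grid of 0.25 h. Differences between the noons were also regressed on the slope at 12 h of the fitted profiles, which gives a shift in h, over the 23043 probes with a large rhythm in all series. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.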

Results

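Transcript levels in field-grown rice leaves were followed through 24 h in 51 samples. There were 12 samples in the July series of early-transplanted plants, which lacks 06:00, and 13 in each of the other 3 series (July late, August early, August late). Each value below is a normalised log2 intensity of 1 probe in 1 sample per time, with no replicates. The share of probes well above background was 60.6% ± 2.32 (SD) in July early, 61.2% ± 1.66 in July late, 58.8% ± 0.96 in August early and 58.2% ± 2.74 in August late. It ranged from 54.6% to 64.0% over the samples. The median SD between spots of the same sequence was 0.13 on the log2 scale, and the median residual SD around the fitted curves was 0.17.

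Early and late samples of most hours lay close together, and each month traced its own loop through the day. The first 3 principal components held 33.9%, 29.7% and 18.2% of the variance. The median correlation across probes was 0.943 between samples of a series and 0.931 between samples of different series. Probes are not independent replicates.

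**Figure D1:**
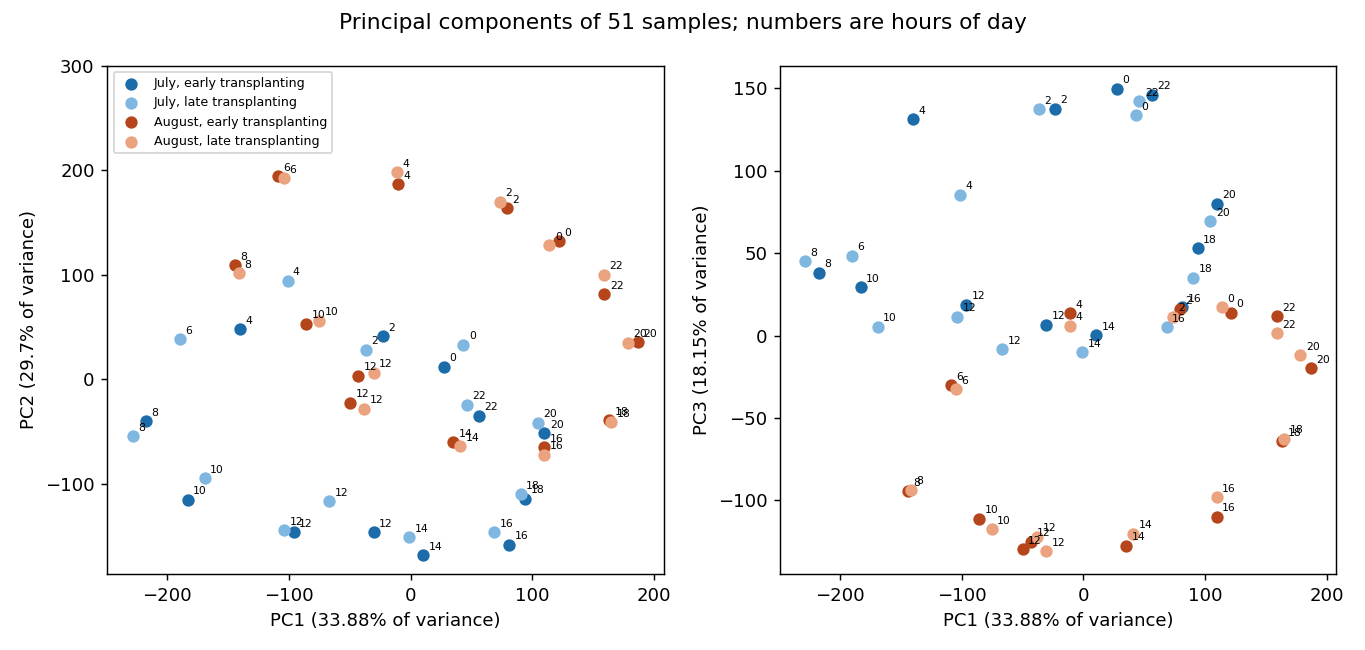
Principal component scores of the 51 samples, PC1 against PC2 and PC1 against PC3, with the share of variance on each axis; each point is 1 sample, coloured by series and numbered by hour of day. Points follow the hour in a loop, with July and August on separate loops and the early and late samples of most hours side by side.

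The first question was which transcripts changed through the day. Most did: 83089 of the 94092 probes (88.3%) had a 24 h rhythm over the 4 series (limma F test). Each series covers a single 24 h, so within it a recurring rhythm cannot be told apart from a change on that day. Rhythms were called for 72817 probes in July early, 72563 in July late, 73378 in August early and 73916 in August late, and for 57671 probes (61.3%) in all 4 series. Large rhythms, with a peak at least 2-fold above the trough, numbered 33931, 31942, 33531 and 34976 in the same order, and 23043 probes had one in every series. In July early, 1709 probes had a range of at least 16-fold, and 1942 did in August early.

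Peaks clustered early in the morning and late in the afternoon. Of the probes with a large rhythm in July early, 31.02% peaked between 3 and 9 h and 33.8% between 15 and 21 h, against 16.3% between 9 and 15 h and 18.8% between 21 and 3 h. In August late the shares were 28.3%, 35.1%, 15.7% and 20.9% for the windows from 3, 15, 9 and 21 h. The 2 h bin around 12 h held the fewest peaks in all 4 series.

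**Figure D2:**
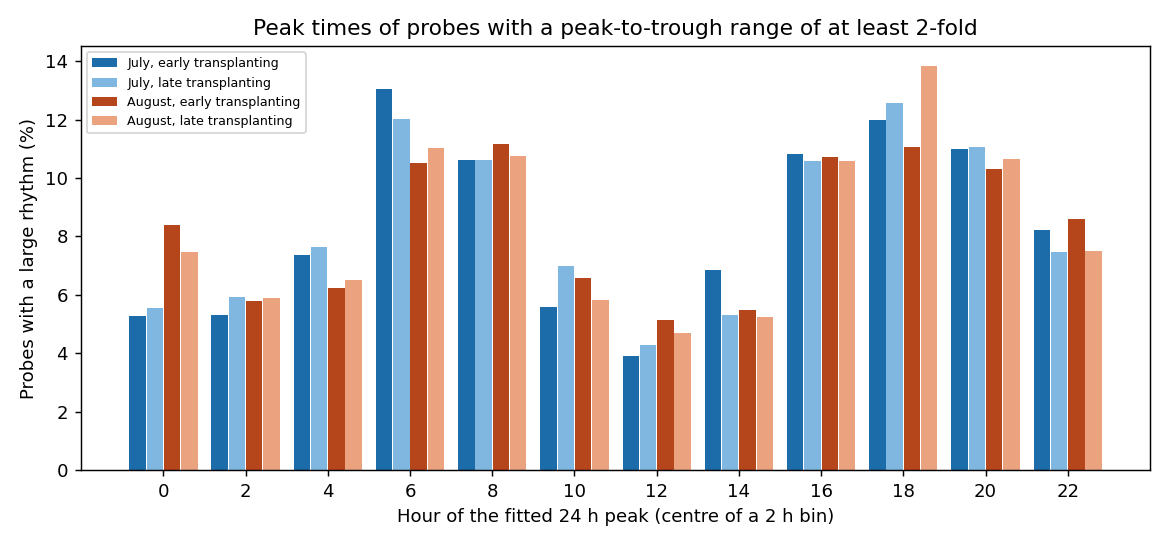
Share of probes with a large rhythm (y axis, percent) by the hour of the fitted 24 h peak (x axis, 2 h bins), with 1 bar per series. The fullest bin was at 6 h in July early, 18 h in July late, 8 h in August early and 18 h in August late, and the emptiest at 12 h in each.

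The largest mean range over the 4 series belonged to probe eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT), which was high from noon to evening. Its range was 10.18 ± 0.57 (SE) on the log2 scale in July early, or 1161-fold, and 10.26 ± 0.50 in August late, or 1227-fold. In August late its measured values ran from 8.24 to 17.78, a narrower span than that fitted range. It peaked at 15.9 h in July early and 15.6 h in August late (adjusted p = 4.51e-16 and 6.38e-18 in limma). Probe eAry2_38876 (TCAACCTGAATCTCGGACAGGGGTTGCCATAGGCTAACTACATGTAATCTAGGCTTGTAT) peaked before dawn, at 2.96 h in July early and 3.74 h in August early, with ranges of 9.40 ± 0.23 and 10.21 ± 0.22. Probes 44kb3_11643 (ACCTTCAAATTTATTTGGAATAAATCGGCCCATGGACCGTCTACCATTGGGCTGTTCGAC) and 44kb3_960 (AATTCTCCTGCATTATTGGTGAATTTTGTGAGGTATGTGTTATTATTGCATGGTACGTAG) peaked after dawn. The range of 44kb3_11643 was 8.19 ± 0.69 in July early and 11.15 ± 0.62 in August early, and its peak moved from 6.4 h to 7.52 h. For 44kb3_960 the range was 8.06 ± 0.64 and 10.85 ± 0.58, and the peak moved from 6.49 h to 7.5 h. They stood well above background in 44 and 48 of the 51 samples, so the background limits their lowest values. The fitted August ranges exceed the span of the measured values. In August early these ran from 6.21 to 16.33 for 44kb3_11643 and from 6.27 to 16.54 for 44kb3_960.

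**Figure D3:**
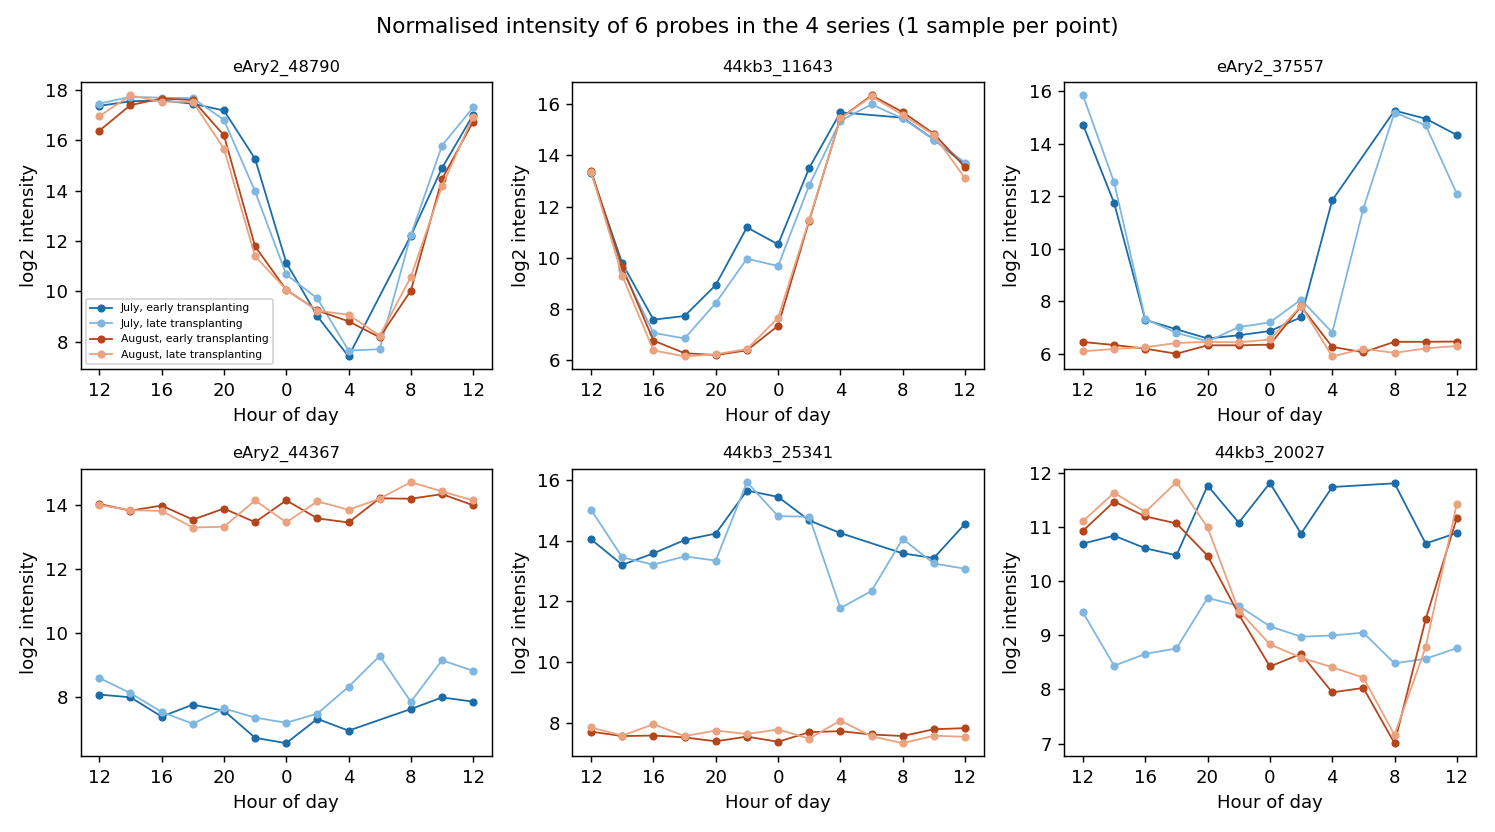
Normalised log2 intensity (y axis) of 6 probes by hour of day (x axis, 12 to 12 h), with 1 point per sample and 1 line per series. eAry2_48790 and 44kb3_11643 swing in every series, eAry2_37557 swings in July alone, eAry2_44367 is higher and 44kb3_25341 lower in August at each hour, and 44kb3_20027 is higher in July early than in July late at each shared hour.

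Rhythms were then compared between the months. They differed for 39937 probes (42.4%), of which 23581 had the larger amplitude in August and 16356 in July. In all, 5517 probes had a large rhythm in 1 month and under 50% of that amplitude in the other, 2768 of them larger in August and 2749 in July. Probe eAry2_37557 (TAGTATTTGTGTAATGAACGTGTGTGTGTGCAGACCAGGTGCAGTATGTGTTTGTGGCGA) had a range of 9.12 ± 0.93 on the log2 scale in July early, with its peak at 9.29 h, and of 0.81 ± 0.88 in August early (adjusted p = 2.01e-07 for the difference in limma). Probe eAry1_24410 (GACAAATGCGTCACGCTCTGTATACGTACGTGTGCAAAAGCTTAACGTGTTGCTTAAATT) had a range of 9.29 ± 0.93 in July early and 0.59 ± 0.95 in August early (adjusted p = 3.56e-07). Its highest August value was 6.90 and its highest July value 15.56. They stood well above background in 29 and 24 of the 51 samples, so the background sets the low end of both ranges. Another probe, 44kb3_37338, overlaps eAry2_37557 in sequence, and its last bases are the first of eAry1_24410. Both may therefore read the same transcript and are not separate examples.

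Peaks came later in August. Over the 23043 probes with a large rhythm in all 4 series the median shift was 0.86 h, and 80.5% of them peaked later in August. The median shift was 1.01 h between the early series and 0.705 h between the late series. It was 0.936 h from July early to August late, at similar days from transplanting, and 0.213 h in July and -0.098 h in August from early to late. By the window of the peak it was 0.861 h from 3 to 9 h, 0.848 h from 9 to 15 h, 0.771 h from 15 to 21 h and 1.1 h from 21 to 3 h. Where both months had a large rhythm and the rhythms differed, 4037 probes moved by more than 2 h, 3546 of them later and 491 earlier in August. The 24 h terms alone, without the 12 h terms, left 25613 probes with differing rhythms, and a block by slide in place of array left 15250. Month cannot be told apart from scan day, or from the single 24 h sampled in it, here or in any comparison of August with July. Set against the fitted profiles of the other month, in a test added after the data were seen, July samples read late by a median of 0.75 h (early) and 0.5 h (late), and August samples read early, at -0.75 h and -0.5 h.

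**Figure D4:**
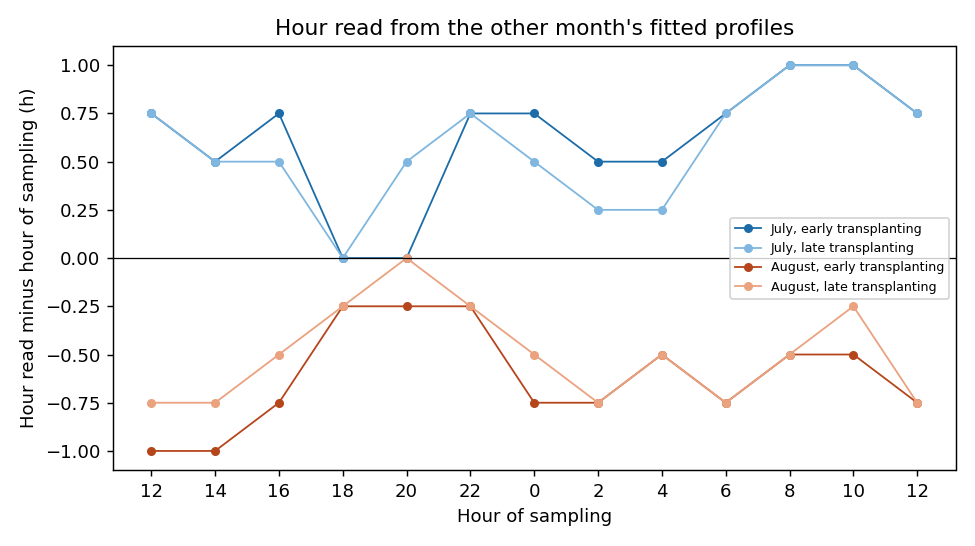
Hour read minus hour of sampling (y axis, h) by hour of sampling (x axis, 12 to 12 h), with 1 point per sample and 1 line per series. July samples lie between 0 and 1 h and August samples between -1 and 0 h.

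Between transplantings few differences in rhythm were called. Rhythms differed for 72 probes. Among probes with a large rhythm in all 4 series, 98.8% in July and 99.5% in August peaked within 2 h of each other. Dye ran with time of day in opposite order in early and late plants. The dye term may therefore take up part of a difference in rhythm, and the count of 72 does not show that rhythms were alike. Probe 44kb3_10393 (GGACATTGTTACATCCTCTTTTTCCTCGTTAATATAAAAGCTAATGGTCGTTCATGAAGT) swung most in July late, with a range of 7.14 ± 0.43 on the log2 scale against 4.18 ± 0.44 in July early, 3.83 ± 0.39 in August early and 4.19 ± 0.39 in August late (adjusted p = 0.0223 in limma). It stood well above background in 30 of the 51 samples, so the background limits the low end of these ranges. Probe eAry1_11529 (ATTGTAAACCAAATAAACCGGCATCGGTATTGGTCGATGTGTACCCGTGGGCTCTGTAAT) had an adjusted p of 0.0283, and its July early range of 1.34 ± 0.41 followed 1 sample at 8.89 where the series mean was 6.67. It stood well above background in 32 of the 51 samples. Probe 44kb3_10393 missed the threshold under 7 alternatives, with adjusted p from 0.0512 to 1, and eAry1_11529 under 6, with adjusted p from 0.0622 to 1. The count of 72 was 0 without the block and 22096 without the dye term, and leaving out single arrays gave 17 to 1834.

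Each month was sampled through a single 24 h. Its samples are successive time points, and the p-values do not measure variation between days of a month. Mean levels over the day were compared between August and July, with both transplantings averaged. They differed for 66276 probes (70.4%), 36049 higher and 30227 lower in August, and by at least 2-fold for 3055 higher and 3880 lower probes. Probe eAry2_44367 (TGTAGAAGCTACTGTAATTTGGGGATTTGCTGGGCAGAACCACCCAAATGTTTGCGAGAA) was 71.1-fold higher in August, at 13.92 ± 0.36 (SD, 26 samples) against 7.77 ± 0.69 (25 samples; adjusted p = 3.57e-26 in limma). Probe 44kb3_38440 (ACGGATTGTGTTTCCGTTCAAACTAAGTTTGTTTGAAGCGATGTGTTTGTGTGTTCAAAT) was 56.9-fold higher, at 12.91 ± 0.40 against 7.08 ± 0.50 (adjusted p = 4.24e-28), and well above background in 23 of 25 July samples. Probe 44kb3_25341 (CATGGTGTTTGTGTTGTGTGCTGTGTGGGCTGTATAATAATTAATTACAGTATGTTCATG) was 79.6-fold lower in August, at 7.63 ± 0.17 against 13.97 ± 0.997 (adjusted p = 5.54e-23). Probe eAry2_36057 (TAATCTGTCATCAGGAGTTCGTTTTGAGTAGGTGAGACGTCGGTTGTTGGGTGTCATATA) was lower, at 6.57 ± 0.85 against 12.77 ± 1.16 (adjusted p = 1.26e-17), and since it stood well above background in only 6 of 26 August samples no fold is given.

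Probes of the night and of midday moved in opposite directions between the months. Of probes peaking between 21 and 3 h, 2856 were higher and 831 lower in August, with a median difference of 0.38 on the log2 scale. Of probes peaking between 9 and 15 h, 647 were higher and 2178 lower, with a median of -0.28. These medians lay between 0.34 and 0.42 and between -0.36 and -0.27 under the 5 normalizations. Over all tested probes, inside and outside these windows, the balance of higher and lower did depend on the normalization. There 54.4% of the called probes were higher in August here and 47.2% with cyclic loess.

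August late and July early, at 81 and 76 days from transplanting, were compared as series of similar age. They differed for 64374 probes, 35229 higher and 29145 lower in August late. Probe eAry2_44367 was 85.0-fold and 44kb3_38440 67.5-fold higher in August late (adjusted p = 7.72e-25 and 1.1e-26 in limma). Probe 44kb3_38440 stood well above background in 10 of 12 July early samples. Probe 44kb3_25341 was 89.5-fold lower (adjusted p = 1.29e-21). Probe eAry2_36057 was lower, at 6.74 ± 1.17 (SD) against 13.32 ± 0.80 (adjusted p = 7.49e-17), and stood well above background in only 4 of 13 August late samples. Probes peaking between 21 and 3 h were again mostly higher in August, 2754 against 817, and those peaking between 9 and 15 h mostly lower, 2134 against 631. With cyclic loess 46.2% of the called probes were higher, against 54.7% here.

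Early transplanting was compared with late within each month, where both samples of an hour shared an array. Differences were many and small. Each transplanting date had 1 series of successive hours per month, so the p-values do not measure variation between plots or plantings. Over both months 21753 probes differed, with a median size of 0.11 on the log2 scale, and 11 of them by at least 2-fold. Probes 44kb3_31676 (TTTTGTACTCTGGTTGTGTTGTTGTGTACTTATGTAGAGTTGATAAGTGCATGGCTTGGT) and eAry2_25014 (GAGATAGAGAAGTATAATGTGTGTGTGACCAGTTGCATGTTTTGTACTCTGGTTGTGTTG) were 2.31-fold and 2.305-fold higher in early plants, with log2 differences of 1.21 ± 0.12 (SE) each (adjusted p = 1.75e-08 and 2.19e-08 in limma). The last 21 bases of eAry2_25014 are the first of 44kb3_31676. Each was higher in 11 of 12 July arrays and in 12 of 13 August arrays. Probes eAry2_20159 (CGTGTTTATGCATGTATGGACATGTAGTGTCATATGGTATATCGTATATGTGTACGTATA) and eAry1_38431 (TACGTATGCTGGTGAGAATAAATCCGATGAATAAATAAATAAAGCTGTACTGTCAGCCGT) were 2.08-fold and 1.99-fold lower in early plants (adjusted p = 2.3e-08 and 7.33e-09). Neither was higher in the early sample on any array, 0 of 12 in July and 0 of 13 in August. The count was 2598 without the array block and 10744 with a block by slide, against 22893 from log ratios within arrays.

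In July 26135 probes differed between early and late plants, 106 by at least 2-fold. Probe 44kb3_20027 (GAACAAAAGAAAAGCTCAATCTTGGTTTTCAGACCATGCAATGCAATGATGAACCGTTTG) was 4.68-fold higher in early plants, at 11.11 ± 0.52 (SD, 12 samples) against 8.96 ± 0.41 (13 samples), and 44kb3_41389 (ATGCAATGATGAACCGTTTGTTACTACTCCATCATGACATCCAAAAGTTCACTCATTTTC) was 3.83-fold higher (adjusted p = 4.23e-14 for both in limma). The last 20 bases of the first are the first of the second. Both were higher in the early sample on 12 of 12 arrays. Probes eAry2_23284 (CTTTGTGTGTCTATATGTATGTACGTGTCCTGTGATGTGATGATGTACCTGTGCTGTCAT) and eAry1_33616 (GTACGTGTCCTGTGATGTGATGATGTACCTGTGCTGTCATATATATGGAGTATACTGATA), which overlap in sequence, were 3.07-fold and 3.01-fold lower in early plants (adjusted p = 3.06e-06 and 3.56e-06) and higher in the early sample on 2 of 12 arrays. Probes peaking between 15 and 21 h were mostly higher in early plants, 1877 against 517, and more were higher than lower under each of the 5 normalizations. Over all probes 40.8% of the calls were higher in early plants here and 60.1% with cyclic loess. The count was 5191 without the block and 15000 with a block by slide.

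In August 4863 probes differed, 27 by at least 2-fold. Probe eAry2_25014 was 2.88-fold and eAry1_50352 (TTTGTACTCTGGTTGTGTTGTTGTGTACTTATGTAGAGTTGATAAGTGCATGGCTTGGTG) 2.78-fold higher in early plants (adjusted p = 2.51e-06 and 7.02e-07 in limma), each on 12 of 13 arrays. They stood well above background in 9 and 7 of the 13 late samples. Probe eAry1_50352 overlaps 44kb3_31676 in sequence and shares 20 bases with eAry2_25014. Probes eAry1_38431 and eAry2_20159 were 2.47-fold and 2.44-fold lower (adjusted p = 4.72e-07 and 3.95e-06). Probes peaking between 3 and 9 h were mostly higher in early plants, 273 against 91, and those peaking between 21 and 3 h mostly lower, 124 against 37. Both directions held under each of the 5 normalizations, but the counts moved, to 944 higher against 45 lower from 3 to 9 h with cyclic loess. From 15 to 21 h the direction itself turned, from 189 higher against 77 lower here to 47 against 328 with cyclic loess. The count was 71 without the block, 738 with a block by slide, 3090 without the filter on dim probes and 3186 without the array of August 7, 18:00.

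The transplanting difference itself differed between the months for 13005 probes, and it was the larger in July for 10496 of these and had opposite signs in the months for 9556. Its median size among these 13005 was 0.167 log2 in July and 0.0594 in August, where the median SE over all probes was 0.0423. Many of the opposite signs may thus rest on August differences near the error. Of the probes called in both months, 835 were lower in early plants in both and 349 higher in both, where independence would give 352 and 308.4. Another 199 were higher in July and lower in August, and 272 the reverse, where it would give 242.4 and 447.9. Across all probes the July and August differences had a Pearson r of 0.155 and a Spearman rho of 0.175. Probes eAry1_27418 (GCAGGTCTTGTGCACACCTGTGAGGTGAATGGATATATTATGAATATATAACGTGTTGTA) and 44kb3_4764 (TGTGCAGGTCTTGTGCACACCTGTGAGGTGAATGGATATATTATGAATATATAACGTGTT), which overlap, changed direction. For eAry1_27418 the means were 11.41 ± 1.37 (SD) in July early, 9.30 ± 2.44 in July late, 6.91 ± 0.89 in August early and 8.31 ± 1.36 in August late, and its interaction was -2.97 ± 0.45 (SE; adjusted p = 5.08e-05 in limma). That of 44kb3_4764 was -2.94 ± 0.46 (adjusted p = 6.84e-05). Both fell to the background in some samples, since they stood well above it in 42 and 40 of 51. For eAry2_23284 and eAry1_33616 it was 1.59 ± 0.32 and 1.52 ± 0.32 (adjusted p = 0.00116 and 0.00157). Probe eAry2_23284 had means of 14.13 ± 1.53 in July early and 15.95 ± 1.31 in July late, and 17.67 ± 0.16 and 17.51 ± 0.19 in August, near the top of the scale. With 75th percentile scaling its interaction was 1.562 (adjusted p = 0.000759). Without the block 449 probes were called and none of these 4 passed, with adjusted p from 0.056 to 0.12, and a block by slide called 3856 probes.

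The last comparison set the second 12:00 against the first, 24 h later, with 1 array of 2 samples at each. In July 12864 probes differed, 3539 of them by at least 2-fold, and in August 97. The first July noon was on an array that stood apart, with an SD over probes of early minus late values of 0.36. Probes eAry2_40456 (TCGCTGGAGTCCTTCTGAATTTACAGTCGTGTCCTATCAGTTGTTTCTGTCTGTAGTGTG) and eAry1_49479 (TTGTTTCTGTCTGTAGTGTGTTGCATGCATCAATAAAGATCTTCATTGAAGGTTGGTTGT) were 83.8-fold and 82.4-fold higher at the second July noon (adjusted p = 0.0217 and 0.00728 in limma). Their means rose from 10.48 to 16.86 and from 10.21 to 16.57, and they share 20 bases. Probe 44kb3_13258, which overlaps both and was chosen after its values were seen, rose by 6.35 (adjusted p = 0.0125). Probes eAry2_20961 (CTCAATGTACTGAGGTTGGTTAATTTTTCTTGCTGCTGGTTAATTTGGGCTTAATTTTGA) and eAry2_13194 (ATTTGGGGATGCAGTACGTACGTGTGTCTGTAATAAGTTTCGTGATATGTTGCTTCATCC) were 7.52-fold and 6.85-fold lower (adjusted p = 0.00613 and 0.0232). Neither eAry2_20961 nor eAry2_13194 had an overlapping probe to compare with. Probes peaking between 15 and 21 h were mostly lower at the second July noon, 800 against 159, and those peaking between 3 and 9 h mostly higher, 774 against 342. The July count ranged from 2004 with 24 h terms alone, where of these 4 probes eAry2_20961 alone still passed, to 28154 without the block. Probe eAry2_40456 missed the threshold under 3 alternatives, with adjusted p from 0.0679 to 0.211.

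In August eAry2_21606 (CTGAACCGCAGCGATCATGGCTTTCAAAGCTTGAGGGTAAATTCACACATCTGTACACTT) was at least 42.9-fold lower at the second noon (adjusted p = 3.99e-23 in limma), where neither sample stood above background. Probe eAry1_23215, which overlaps it and was chosen after its values were seen, differed by -0.21 (adjusted p = 0.6). Probe eAry2_09126 (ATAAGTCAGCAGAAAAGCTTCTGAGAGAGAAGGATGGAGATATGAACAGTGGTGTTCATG) was at least 5.62-fold lower (adjusted p = 0.00275). Probes eAry1_28779 (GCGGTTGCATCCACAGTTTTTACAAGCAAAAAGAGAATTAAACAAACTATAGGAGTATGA) and eAry1_29505 (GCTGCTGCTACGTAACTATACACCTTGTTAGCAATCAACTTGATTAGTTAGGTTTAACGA) were higher, at least 2.7-fold for the first and 2.74-fold for the second (adjusted p = 3.17e-05 and 6.64e-05), and eAry1_29505 missed the threshold under 2 alternatives (adjusted p = 0.11 and 0.596). Probes eAry2_09126, eAry1_28779 and eAry1_29505 had no overlapping probe to compare with, so a spot defect cannot be excluded for them. The August count ranged from 30 to 5517 under the alternatives whose fit converged. Whether the change from noon to noon differed between the months was not tested.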

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

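The tests of dye bias, of sunset and of plant age on the peak times, the hour read and the slopes at the July noons, and the runs without 2 July arrays or without single arrays were chosen only after the results were seen.

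The 3 results named here stood out because an effect differed between groups by a test of the difference itself. The difference between early and late transplanting was not the same in July and August for 13005 probes. Rhythms differed between the months for 39937 probes and between the transplantings for 72 probes.

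For the transplanting-by-month difference, 1 of 100 groupings, the real one, gave as many probes and the highest other gave 2537. A random grouping is therefore unlikely to give that count. For rhythms that differ between months, 2 of 100 groupings gave as many: another grouping, which exchanged the months at some of the hours, called 47101 probes. Such a grouping may turn the difference in level between the months into a pattern over the hours, so its count points to a structure of the samples, which was not tested. For rhythms that differ between transplantings chance cannot be excluded, since 12 of 100 groupings gave at least 72 probes and the highest other gave 6355, many times the real count, which points to a structure of the samples that was not tested.

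For each of the other results below, 1 of 100 groupings, the real one, gave as many probes. A random exchange of these labels thus rarely gives such a count. All groupings used the same days and plantings, so they do not measure variation between days or plantings. With the hours exchanged among the arrays of a month, the highest other count was 19483 for rhythms over all series against 83089. It was 14043 against 72817 in July early, 13480 against 72563 in July late, 24400 against 73378 in August early and 23143 against 73916 in August late. With the months exchanged at single hours, it was 35725 against 66276 for August and July. With early and late exchanged on single arrays, it was 3993 against 21753 for both months, 13520 against 26135 for July and 114 against 4863 for August. For the series of similar age it was 51469 against 64374.

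More probes differed between transplantings in July than in August, 26135 against 4863. The July arrays at the first 12:00 and at 04:00 stood apart, with an SD over probes of early minus late values of 0.36 and 0.43 against 0.17 to 0.31 on the other arrays, but without them the July count was still 3.6 times the August count. Dye ran with time of day in both months, but log ratios within arrays, with a term for the dye orientation, gave a ratio of 7.14, so neither is likely to be the whole cause. Plants in July were 76 and 53 days from transplanting and in August 104 and 81 days, and a difference by age stays open as untested. Month cannot be told apart from scan day, which stays open as well. The model held 1 spread per probe for both months, so a spread that differs between them was not allowed for. With early and late exchanged on single arrays, the highest other count was 13520 in July and 114 in August. Whether a larger spread in July raised its count was not tested.

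Peaks were later in August than in July by a median of 0.86 h. Without the 2 July arrays the median shift was 0.84 h, and the smaller of the shifts of the early and the late pair of series, in which dye ran in opposite order over the hours, was 0.705 h, which argues against both as the whole cause. Sunset comes earlier in August than in July, but probes peaking between 15 and 21 h moved later, by a median of 0.771 h, so peaks that follow sunset could not give this shift. August late and July early, at 81 and 76 days from transplanting, were 0.936 h apart, which argues against age from transplanting as the whole cause, though it may play a part, as may the later sunrise in August and the weather of the days sampled, which were not tested. The shift kept its direction under each of the 13 alternatives run, from 0.73 h to 0.884 h. The scan day cannot be told apart from the month, and none of these alternatives separates them.

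In July 12864 probes differed between the noons and in August 97. The first July noon was on 1 of the 2 July arrays that stood apart. Its SD over probes of early minus late values was 0.36, against 0.234 at the second July noon. At the August noons this SD was 0.217 and 0.21. The July comparison rests on that array, and the part it plays in the July count was not tested. Spot defects on single arrays are unlikely to explain the July count: of its called probes with an overlapping probe, 97.8% moved the same way as that probe (95% interval, exact, 97.4% to 98.1%). For August the share was 84.62% (71.9% to 93.1%) of the 52 called probes with an overlapping probe, too few to decide, and eAry2_21606, whose overlapping probe moved by -0.21, may be a defect of 1 spot. A second noon at an earlier point of the daily cycle stays open: the largest difference between the hours read at the 2 July noons from August profiles was 0 h, but probes peaking from 15 to 21 h were mostly lower and those from 3 to 9 h mostly higher, and profile slopes at 12 h gave shifts of -1.25 h (early) and -0.673 h (late) with July profiles and of -0.624 h and 0.0347 h with August profiles. The July profiles were fitted to the same July samples, so the shifts they gave are not independent of the noon values. At the August noons the shifts were -0.248 h (early) and -0.265 h (late) with August profiles. With July profiles they were -0.00716 h and -0.0581 h. Each July series changed dye between its 2 noons, in opposite order in early and late plants, and each August series kept its dye. The noon differences set against the slopes were not corrected for dye, so the July and August shifts are not directly comparable. Each noon was on 1 array, so the day's conditions cannot be told apart from an effect of the array, and no biological explanation was tested.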

How the results depend on the processing

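The run without 2 July arrays, leave-one-out over the 26 arrays and the other correlation for the noon comparison were chosen after seeing the data; the other alternatives were planned. Of 205 alternative counts, 174 stayed within 1.5 times the reported count and 31 did not. The named probes gave 561 alternative values: 537 stayed past the threshold, 24 missed it, and 0 changed sign. Ranges and rhythm differences among them are sizes without a sign, so a reversal could not be counted for those. Rhythm counts in all series together and in each series, the month comparison and the comparison at similar age stayed within 1.5 times under every alternative run, from 65862 to 88798 probes for rhythms in all series and from 50573 to 72121 for August against July.

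The cause of the changes with the block was not tested. Without a block the counts were 2598 for transplanting in both months, 5191 in July, 71 in August, 449 for its difference between months, 28154 for the July noons, 5517 for the August noons and 0 for rhythms that differ between transplantings, where limma gave 1008 probes at an unadjusted p under 0.05. With the slide as block they were 10744, 15000, 738, 3856, 5360, 45 and 4 in the same order, and 15250 for rhythms that differ between months. Log ratios within arrays, with the array as replicate block, gave 22893, 28487, 3988 and 14184 for the transplanting results.

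Without the filter on dim probes, which tests more probes, the counts were 3090 for transplanting in August, 7823 for its difference between months, 593 for the August noons and 19 for rhythms between transplantings. With probes above background in all 51 samples, 33 were called for the August noons. With 24 h terms alone they were 2004 for the July noons, 30 for the August noons and 25613 for rhythms between months. The authors' processed signals gave 54 for the August noons. Scaling to the 75th percentile gave 21237 for the July noons, with the median of all probes at -0.197, and 157 for rhythms between transplantings. Rhythms between transplantings numbered 22096 without the dye term, 5893 with sample weights, 113 without the second 12:00 and 20 without the 2 July arrays. Without the dye term, a dye effect can count as a difference in rhythm, since dye ran in opposite order in early and late plants. Sample weights gave 21147 for the August noons, from a weight estimation that did not converge, so that this count is not reliable. For none of these was the cause tested. With the other correlation the noons gave 9535 probes in July and 66 in August.

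Leave-one-out gave 17 to 1834 for rhythms between transplantings, beyond 1.5 times for 20 of 26 arrays, and 3186 to 5741 for transplanting in August, beyond it without the array of August 7, 18:00. Leave-one-out was not run for the noons, each of which has 1 array. The other results it was run for stayed within 1.5 times, among them 18040 to 24410 for transplanting in both months, 19365 to 27424 in July and 9276 to 15482 for its difference between months.

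The balance of higher and lower probes moved with the normalization. Among called probes 44.5% were higher in early plants in both months, against 59.5% with cyclic loess and 57.4% with 75th percentile scaling; for July the shares were 40.8%, 60.1% and 56.8%, and for the difference between months 58.7%, 39.0% and 41.2%. Loess within arrays gave 45.8% for the last. At the July noons 47.9% were higher, against 26.3% with 75th percentile scaling, and at the August noons 22.7%, against 39.8% with cyclic loess.

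Set tests with an estimated correlation, means over the probes of a gene and shifts of gene lists were not run, since no probe was matched to a gene. Dim probes were limited by signal over background: 54.6% to 64.0% of probes stood well above it in a sample.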

Other observations

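All tests in this part were chosen after the data were seen.

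Probes whose sequences share 25 bases are likely to read the same transcript and gave a check on the peak times. No probe was matched to a gene, so this was not tested. Of 10770 such pairs with a large rhythm in both probes, 99.6% peaked within 2 h of each other, with a median difference of 0.083 h. Called probes with an overlapping probe moved the same way as that probe in 99.5% of cases for transplanting in both months and 99.3% for August against July.

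Probes to opposite strands of the same stretch formed 923 pairs, of which 74 had a large rhythm in both probes. Their peaks lay a median of 7.24 h apart and 29.7% were within 2 h, against 5.95 h and 18.4% for 20000 random pairs of probes with a large rhythm. Which strand of a pair is transcribed is not known from the files.

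Each sample's hour was read from the fitted profiles of the other month. All 51 samples were read within 1 h of the hour of sampling. The differences were smallest at 18 and 20 h. No sample was read at an hour that would point to an exchange of labels between hours.

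Counted by groups of probes joined by shared sequence, 54195 of 61272 groups had a rhythm over the 4 series, 43841 differed between August and July, 14752 differed between transplantings over both months, 17618 in July and 3525 in August.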
